A study of Mus musculus with 6 samples.

How the data were processed

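The series measured RNA in mouse hepatic tissue by RNA sequencing, in 3 libraries of wild type control mice and 3 libraries of mice with a hepatic knockout of FTO, an enzyme that removes methyl groups from N6-methyladenosine (m6A) in RNA. Total RNA was isolated with Trizol, treated with DNase, purified on RNeasy columns and made into Illumina libraries, per the labels' protocols. Groups were taken from the genotype label of each sample. The replicate numbers used here follow the order of the samples and pair no libraries. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

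The deposited table gave FPKM (fragments scaled by transcript length and by the number of mapped fragments) for 25690 genes under Ensembl identifiers, and the unit was read from the values and from the submitters' processing notes. Those notes name TopHat2 2.1.0, HTSeq and Cufflinks 2.2.1 and the genome build mm10, without saying what each was used for; the annotation release was not given in the sources used here. Of the deposited FPKM values, 50.7% had more than 6 significant digits, and 70.4% of the doubled values had at most 6, as the mean of 2 Cufflinks values would give; what was averaged is not given in the sources used here. Symbols and coordinates came from GENCODE M21 (GRCm38, the assembly of mm10), which matched 24807 identifiers, and 46 rows carried a suffix on a repeated identifier.

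Because low FPKM values stood at multiples of what 1 fragment is worth, depth was inferred from 964 genes with a single transcript of 3000 to 8000 bases. This gave 34690000, 36550000 and 34980000 fragments for wild type replicates 1, 2 and 3 and 34760000, 34140000 and 42530000 for FTO knockout replicates 1, 2 and 3. Each is a median over the 49 to 60 values per library that gave 25000000 to 50000000 fragments if read as 1 fragment, a window set after the values were seen. The 10th to 90th percentiles of FTO knockout replicate 3 were 28410000 to 43260000, with 45 of 54 values within 5% of the median, and those of the other libraries lay between 32730000 and 37270000. Of the 132 to 143 values per library under 3.5 steps, 75.0% to 82.2% lay within 0.15 of a whole step. At the lowest of the 6 estimates a transcript of 2 kilobases at 1 FPKM corresponded to 68 fragments. Counts were not recovered for the whole table, so no count model was used. The FPKM sums ran from 843847 to 1076602, and transcripts of the mitochondrial genome held 23.2% to 30.3% of the sum.

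An exact 0 in this table can be a failed estimate. Albumin (Alb) was listed at 0 in wild type replicate 1 and FTO knockout replicate 3 and at 25046 FPKM or more in the other 4 libraries. In all, 31 genes were listed at 0 in a library and at 10 FPKM or more in another, 15 of them genes of the major urinary protein (Mup) family, and for these library values are given in place of means. Genes with near-identical copies, such as the Mup, Cyp2b, Ces1, Serpina1, Raet1 and histone families, and overlapping genes have uncertain values, since it is not given how reads that fit several genes were assigned.

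The comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) on log2(FPKM + 1), for the 10405 genes with a mean of at least 1 FPKM over the 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes; folds are ratios of mean FPKM. Gene lists were tested with camera at a preset correlation of 0.01 between genes, for the 41 of 46 lists with at least 4 tested members, and adjusted over the lists. The lists (944 symbols, 910 of them in the table and 703 tested) cover liver pathways, cell types and sample quality. The design, the lists, the rule for named genes and the settings listed next were fixed before the data were examined.

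The genes named are Fto, Foxo1, G6pc and Pck1; per direction the 12 largest changes among called genes whose groups did not overlap, without predicted models; up to 4 members by smallest p of each list that had a called member or was called itself; and sex chromosome markers and the 3 most abundant genes. Other genes named were chosen after their values were seen, and this is stated where they appear. The settings fixed in this way were median ratio size factors, quantile normalization, robust empirical Bayes, no filter on low values, a pseudocount of 0.1, leaving out each library in turn, and for lists an estimated correlation and the fry rotation test. Removal of a transcript length trend per library (lowess, span 0.3), leaving out the genes listed at 0 and, for counts and medians per list, leaving out each library were added after the data were seen. On simulated data for this comparison with 10405 genes, 61 of 100 genes changed by a log2 fold of 1 and 96 of 100 changed by a log2 fold of 2 were called, with 5 false calls among 162. The simulated noise was independent between genes, and no simulated library stood apart as wild type replicate 3 did. In the real data, estimated correlations between genes within lists reached 0.86. The share of false calls may therefore not carry over to the real calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.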

Results

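RNA of mouse hepatic tissue was sequenced in 3 wild type libraries and 3 libraries of mice with a hepatic FTO knockout, and the series asks how the liver transcriptome differs between these groups. FTO is an RNA demethylase that acts on m6A. Of 25690 genes, 10405 had a mean of at least 1 FPKM and were tested. The inferred depth was 34140000 to 42530000 fragments per library. For the 774 genes between 100 and 1000 FPKM, the median absolute log2 difference between knockout libraries was 0.12 to 0.19. It was 0.142 between wild type replicates 1 and 2, and 0.414 and 0.289 between wild type replicate 3 and those libraries, so wild type replicate 3 stood apart within its group. Of the 10405 tested genes, 0 had identical values above 0 in any pair of libraries. Of the most abundant genes, mt-Atp8 had 91308 ± 5022 FPKM in wild type and 79947 ± 4533 FPKM in knockout (SD, n = 3 each). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 1.97 FPKM or more in all 6 libraries, and Xist, expressed from the inactive X chromosome, was at 0.0662 FPKM or less.

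Fto (ENSMUSG00000055932, chromosome 8, 91313525 to 91668439, mm10) fell in the knockout. Its level was 6.36 ± 0.324 FPKM in wild type and 2.76 ± 1.02 FPKM in knockout (SD, n = 3 each), a log2 change of -1.0 with an SE of 0.19 and an adjusted p of 0.0386 in limma. Knockout replicates 1, 2 and 3 held 28.2%, 60.2% and 41.8% of the wild type mean, and all 3 lay below all 3 wild type libraries. The value covers the whole gene, so a deleted exon was not resolved. The call was lost when wild type replicate 1 or 2 or knockout replicate 1 or 3 was left out, with adjusted p-values of 0.0804, 0.113, 0.0662 and 0.146, and with no filter on low values (0.0975). Of 22 tested m6A writers, erasers and readers, 0 were higher, 1 was lower (Fto) and 21 were not called, and adjusted over the list alone 0 were higher and 1 was lower. The median of this list was 0.03 and its mean -0.03 on the log2 scale, and the median ran from -0.04 without wild type replicate 3 to 0.09 without wild type replicate 1.

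Genes that fell in knockout included Cidea, Cidec and Plin4, which encode lipid droplet proteins, the fatty acid transporter gene Cd36, the desaturase gene Scd1 and the P450 genes Cyp2b9 and Cyp17a1. Genes that rose included Cyp7a1 and Cyp7b1 of bile acid synthesis, the complement genes C6 and C8b, the fatty acid binding protein gene Fabp5 and the lipase gene Lpl. In all, 115 genes were higher and 172 were lower in knockout, and the groups of all 287 did not overlap. Among all tested genes 24.5% did not overlap, against 10% by chance. Changes of at least 1 on the log2 scale were seen for 71 of the higher and 79 of the lower genes, and 13 higher and 15 lower genes were predicted models. Without wild type replicate 3, 312 genes were higher and 240 lower, so that the share of higher genes moved from 40.1% to 56.5%. Without wild type replicate 2 the counts were 62 and 53, without knockout replicate 1 they were 64 and 65, and without knockout replicate 3 they were 43 and 49.

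**Figure D1:**
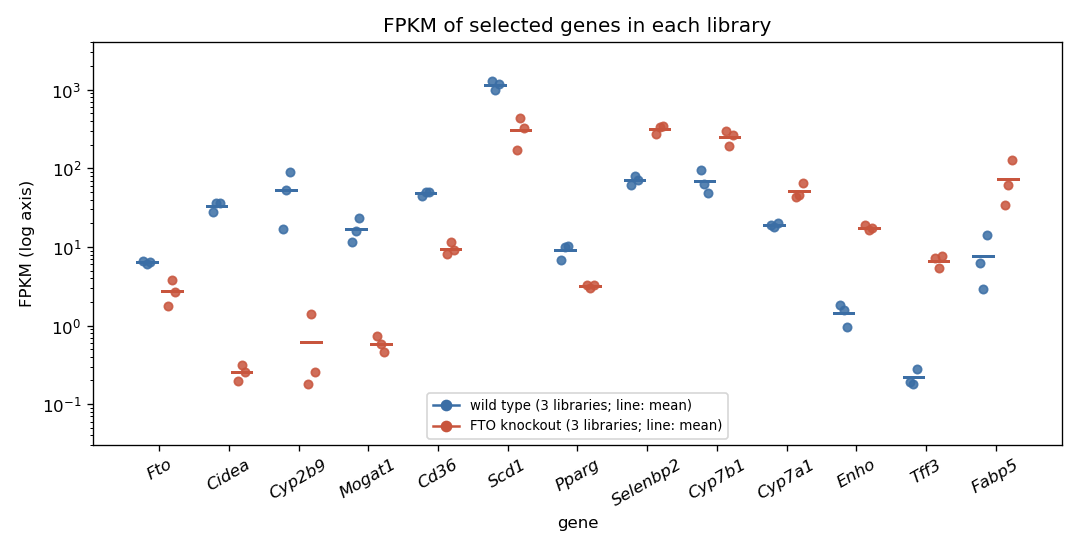
FPKM on a log axis for 13 genes in each of the 6 libraries, with points for libraries and lines for group means. All 3 knockout libraries lie below the wild type libraries for Fto, Cidea, Cyp2b9, Mogat1, Cd36, Scd1 and Pparg and above them for the other 6 genes.

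Among the largest decreases was Cidea, which encodes a lipid droplet protein (chromosome 18, 67343604 to 67367785). It fell from 33.4 ± 4.91 to 0.257 ± 0.0596 FPKM (SD, n = 3 each; log2 change -4.77, SE 0.13, adjusted p 6.65e-06). The related Cidec fell 6.21-fold to 5.47 ± 2.91 FPKM, and Mogat1, a monoacylglycerol acyltransferase, fell 28.9-fold to 0.589 ± 0.137 FPKM. Cyp2b9, a P450 enzyme, fell from 53.7 ± 36.9 to 0.610 ± 0.679 FPKM (adjusted p 0.00597). The fatty acid transporter gene Cd36 fell 5.08-fold, from 48.4 ± 2.94 FPKM. The metallothionein genes Mt1 and Mt2 fell 6.83-fold and 13.1-fold, and Lgals1, which encodes galectin-1, fell 6.38-fold. The carboxylesterase gene Ces1g fell 5.03-fold, and the NKG2D ligand genes Raet1d and Raet1e, which overlap in the annotation, fell 5.80-fold and 7.83-fold. Mup17 was listed at 0 in all knockout libraries and at 18963, 11432 and 3074 FPKM in wild type replicates 1, 2 and 3. All 15 Mup genes with such zeros were at 0 in every knockout library, so its decrease may come from failed estimates.

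Among the largest increases was Fabp5, which encodes a fatty acid binding protein (chromosome 3, 10012548 to 10016607). It rose from 7.74 ± 5.80 to 73.9 ± 47.7 FPKM (SD, n = 3 each; log2 change 3.12, SE 0.57, adjusted p 0.0359). Enho, which encodes the secreted peptide adropin, rose 12-fold to 17.6 ± 1.18 FPKM, and the trefoil factor gene Tff3 rose from 0.219 ± 0.0564 to 6.72 ± 1.20 FPKM. The noncoding RNAs Meg3 and Rian, from one imprinted region of chromosome 12, rose 15.1-fold and 14.1-fold to 9.97 ± 6.22 and 7.65 ± 3.37 FPKM. Derl3 rose 8.51-fold, Cd207 9.73-fold, Cib3 10.9-fold and Cystm1 4.27-fold. Selenbp2 rose 4.46-fold to 317 ± 41.3 FPKM and Serpina1e 4.25-fold to 8246 ± 1332 FPKM. Mup20 was at 6043, 5053 and 5257 FPKM in wild type replicates 1, 2 and 3 and rose 4.04-fold, to 33731, 14290 and 17962 FPKM in knockout replicates 1, 2 and 3.

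One list joins genes of fatty acid oxidation and targets of PPAR alpha. Of its 33 tested genes 0 were higher, 7 were lower and 26 were not called, and adjusted over the list alone 0 were higher and 11 lower. Camera called the list toward lower values with an adjusted p of 6.93e-07, and the adjusted p was 0.487 with an estimated correlation. The transporter gene Cd36 is among the lower genes of this list, so they are not all genes of oxidation. The thioesterase gene Acot3 fell 3.46-fold to 7.33 ± 0.505 FPKM, Acaa1b, a peroxisomal thiolase, fell 2.56-fold to 469.7 ± 70.6 FPKM, and Aldh3a2 fell 1.98-fold. Of 24 genes of fatty acid and triglyceride synthesis, 0 were higher, 3 were lower and 21 were not called, with 6 lower and 0 higher adjusted over the list alone. Scd1, the stearoyl-CoA desaturase, fell from 1150.4 ± 144 to 311 ± 133 FPKM, and Me1, the malic enzyme, fell 2.71-fold. Insig2, also counted among the 3 lower genes, fell 2.0-fold, but it encodes a protein that restrains lipid synthesis, not an enzyme of it. The 3 lower genes therefore do not all point toward less synthesis. Camera gave an adjusted p of 0.000292, and 0.527 with an estimated correlation.

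Of 27 genes of lipoproteins and lipid droplets, 1 was higher, 3 were lower and 23 were not called, and adjusted over the list alone 2 were higher and 5 lower. The lower genes were Cidea, Cidec and the perilipin gene Plin4, which fell 4.69-fold to 2.38 ± 0.992 FPKM. Lpl, the lipoprotein lipase gene, rose 2.19-fold to 2.60 ± 0.497 FPKM. This list had an adjusted p of 0.000861, and of 0.472 with an estimated correlation. Of 7 tested adipocyte genes 3 were lower, 0 were higher and 4 were not called, with 4 lower and 1 higher adjusted over the list alone. Cidea, Cfd and Pparg fell, Cfd 5.62-fold and Pparg, which encodes a nuclear receptor of fat storage, 2.86-fold to 3.17 ± 0.164 FPKM. The adipocyte genes Adipoq, Plin1 and Lep were at 0.233 FPKM or less in all 6 libraries. For the adipocyte list the adjusted p was 1.67e-05, and 0.423 with an estimated correlation.

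**Figure D2:**
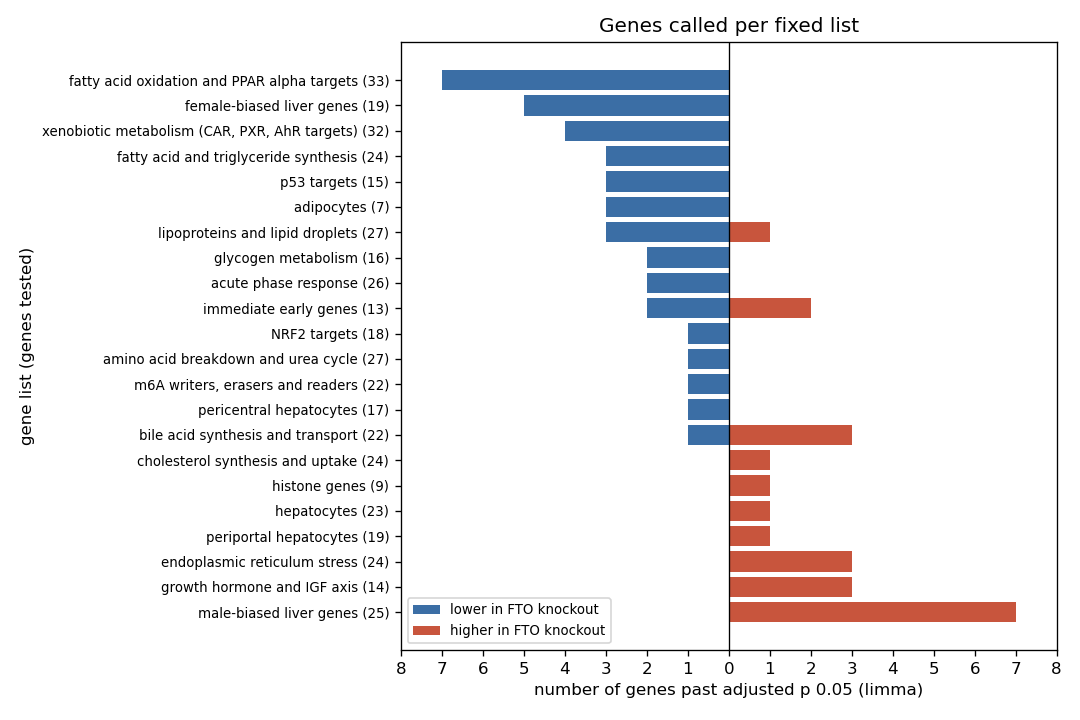
Number of genes past an adjusted p of 0.05 in limma, lower to the left and higher to the right, for each fixed list with a called gene, with the genes tested in parentheses. The list of fatty acid oxidation and PPAR alpha targets has 7 lower genes, female-biased genes have 5, and male-biased genes have 7 higher genes.

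Of 25 male-biased liver genes, 7 were higher, 0 lower and 18 not called, and adjusted over the list alone 12 were higher and 2 lower. C8b and C6, which encode complement components, rose 2.70-fold and 3.21-fold, and Cyp7b1, an oxysterol hydroxylase gene, rose 3.66-fold to 254 ± 57.7 FPKM. For this list the adjusted p was 1.36e-05, and 0.423 with an estimated correlation, and 3 of its Mup genes were listed at 0 in some libraries. Of 19 female-biased genes, 5 were lower, 0 higher and 14 not called, and adjusted over the list alone 7 were lower and 0 higher. Besides Cyp2b9 and Acot3, Cyp17a1 fell 4.58-fold and Cyp2b13 fell from 3.37 ± 2.17 to 0.0370 ± 0.0480 FPKM. Camera gave these genes an adjusted p of 0.000861, and 0.472 with an estimated correlation. Without wild type replicate 3, 10 male-biased genes were higher and 3 female-biased genes were lower. Of 14 genes of the growth hormone and IGF axis, 3 were higher, 0 lower and 11 not called, with 4 higher and 0 lower adjusted over the list alone. Socs2 rose 3.45-fold, Igfbp2 2.27-fold and Onecut1 3.63-fold, and the adjusted p of the list was 0.0348, and 0.472 with an estimated correlation. Log2 changes were above 0 for 7 of the 14 genes and below 0 for 7, with a median of 0.12, so the list had no common direction.

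Genes of 3 enzymes of bile acid synthesis rose. Of 22 genes of bile acid synthesis and transport, 3 were higher, 1 was lower and 18 were not called, and adjusted over the list alone 4 were higher and 5 lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 2.71-fold from 19 ± 1.22 to 51.5 ± 11.9 FPKM, and Cyp7b1 and Cyp2c70 also rose, Cyp2c70 2.30-fold. The transporter gene Abcc2 fell 1.60-fold. Camera gave this list an adjusted p of 0.915, and its median (-0.11) and mean (0.03) on the log2 scale differed in sign. The median was -0.24 without wild type replicate 3 and -0.13 to -0.04 without any other library, and the mean was -0.03 without wild type replicate 3. Of 24 genes of cholesterol synthesis and uptake, 1 was higher (Sqle, 3.09-fold), 0 were lower and 23 were not called, with 5 higher and 0 lower adjusted over the list alone. Camera gave an adjusted p of 0.00183, and 0.527 with an estimated correlation. Of 32 genes of xenobiotic metabolism, 4 were lower, 0 higher and 28 not called, with 6 lower and 0 higher adjusted over the list alone. Cyp2c38 fell 2.93-fold and Cyp3a25 1.60-fold. The other lower genes were Cyp2b9 and Cyp2b13, which also count among the lower female-biased genes. Both belong to a family of near-identical copies with uncertain values. For xenobiotic metabolism the adjusted p was 0.00172, and 0.527 with an estimated correlation.

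Of 23 genes of gluconeogenesis 0 were called by limma, with 0 higher and 5 lower at an unadjusted p under 0.05 and 0 higher and 2 lower adjusted over the list alone. G6pc, the glucose-6-phosphatase gene, was at 163 ± 32.8 FPKM in wild type and 100.2 ± 30.9 FPKM in knockout (SD, n = 3 each; adjusted p 0.161), with overlapping libraries. Pck1 was at 776 ± 90.5 and 701 ± 94.8 FPKM (adjusted p 0.675), and Foxo1, a transcription factor that activates both, was at 4.89 ± 0.976 and 4.92 ± 0.217 FPKM (adjusted p 0.958). For gluconeogenesis the adjusted p was 0.00565 toward lower values, and 0.472 with an estimated correlation. Of 23 FOXO1 targets in liver 0 were called, with 2 higher and 5 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Of 16 genes of glycogen metabolism, 2 were lower, 0 higher and 14 not called, with 6 lower and 0 higher adjusted over the list alone. Ppp1r3c and Ppp1r3b, which encode subunits that target phosphatase to glycogen, fell 2.05-fold and 1.55-fold. For glycogen metabolism the adjusted p was 0.000861, and 0.472 with an estimated correlation.

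Of 15 tested p53 targets, 3 were lower, 0 higher and 12 not called, with 5 lower and 0 higher adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a fell from 5.29 ± 2.27 to 0.441 ± 0.155 FPKM, and Ccng1 fell 2.09-fold. For p53 targets the adjusted p was 0.000573, and 0.472 with an estimated correlation. Of 24 genes of endoplasmic reticulum stress, 3 were higher, 0 lower and 21 not called, with 10 higher and 0 lower adjusted over the list alone. Sdf2l1 rose 2.62-fold, Creld2 1.88-fold and the transcription factor gene Xbp1 1.69-fold. The adjusted p of this list was 1.84e-05, and 0.472 with an estimated correlation. Of 26 acute phase genes 2 were lower, 0 higher and 24 not called, with 2 higher and 2 lower adjusted over the list alone. The lower genes were Mt1 and Mt2, which bind metals, while 22 of the 26 had higher means in knockout. The adjusted p of this list was 0.00172 toward higher values, and 0.527 with an estimated correlation.

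Ribosomal protein genes had higher means in knockout for all 34 tested, with 0 called by limma, 18 higher and 0 lower at an unadjusted p under 0.05, and 8 higher and 0 lower adjusted over the list alone. The median log2(FPKM + 1) of these genes was 8.46, 8.54 and 9.07 in wild type replicates 1, 2 and 3 and 9.18, 8.91 and 9.08 in knockout replicates 1, 2 and 3, so wild type replicate 3 lay at the level of the knockout libraries. Rplp0 was at 234 ± 18 and 337 ± 13.2 FPKM in wild type and knockout (adjusted p 0.0650). The adjusted p of the list was 2.55e-10, and 0.527 with an estimated correlation. Of 17 genes of Kupffer cells and macrophages 0 were called by limma, with 8 higher and 0 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Marco was at 1.20 ± 0.368 and 4.52 ± 2.60 FPKM and Lyz2 at 25.9 ± 18.8 and 62.5 ± 18.8 FPKM in wild type and knockout. The adjusted p of this list was 1.36e-05, and 0.527 with an estimated correlation. Without wild type replicate 3, 23 ribosomal protein genes and 9 Kupffer cell genes were higher and 0 of either list were lower. That library had the highest ribosomal level of the wild type libraries, so leaving it out was bound to raise this difference. The median log2 change of the Kupffer cell genes also rose, from 0.81 to 1.11. With any other single library left out, 0 ribosomal protein genes were called. Among Kupffer cell genes 1 was then higher without knockout replicate 2 and 0 otherwise. Of 23 hepatocyte genes 1 was higher (Ahsg, 1.56-fold), 0 were lower and 22 were not called, with 4 higher and 0 lower adjusted over the list alone and adjusted p-values of 0.00307 and 0.423, the latter with an estimated correlation.

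Of 13 immediate early genes, 2 were higher, 2 were lower and 9 were not called, with 3 higher and 2 lower adjusted over the list alone. Junb and Ier2 rose 2.07-fold and 1.89-fold, and Dusp1 and Gadd45g fell 1.84-fold and 3.58-fold. Both genes that rose lie on chromosome 8 between 84249906 and 85075162 in mm10, where 10 of 24 tested genes were called, 2 higher and 8 lower. That segment starts to the left of Fto and ends 6.24 Mb from it. Within 10 Mb of the centre of Fto, 14 of 100 other tested genes were called (14%), against 2.75% of all tested genes. The segment supplied 10 of these 14 calls, and it was picked as the 1 Mb window with the most calls. The 14% therefore mostly repeats that choice. The other called genes were Ces1b, Ces1g, Mt1 and Mt2. The 3 tested genes next to Fto were not called by limma, with 0 at an unadjusted p under 0.05.

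**Figure D3:**
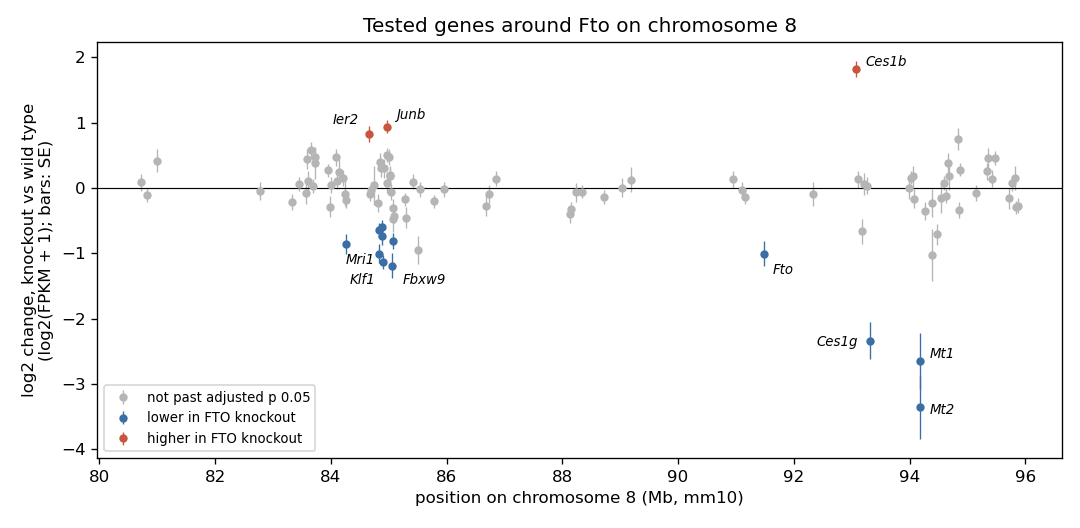
Log2 change of tested genes along chromosome 8 around Fto, against position in Mb of mm10, with bars for the SE and colours for called genes. The 10 called genes between 84249906 and 85075162 lie to the left of Fto, and Ces1b, Ces1g, Mt2 and Mt1 to its right.

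Of 22 genes of glycolysis and glucose uptake, 6 of ketone body synthesis and 16 heat shock genes, 0 were called by limma. At an unadjusted p under 0.05, glycolysis had 1 higher and 6 lower genes, ketone body synthesis 0 higher and 3 lower, and heat shock genes 5 higher and 0 lower. Adjusted over the list alone, ketone body synthesis had 3 lower genes and the other lists 0. Camera called glycolysis and ketone body synthesis toward lower and heat shock genes toward higher values (adjusted p 0.00307, 0.0183 and 0.000861), and with an estimated correlation the adjusted p-values were 0.591, 0.472 and 0.527. NRF2 targets (18 tested), genes of amino acid breakdown and the urea cycle (27) and pericentral hepatocyte genes (17) had 1 lower gene each, which were Ces1g, Bhmt (2.06-fold) and Aldh3a2. Periportal hepatocyte genes (19) and histone genes (9) had 1 higher gene each, Rnase4 (1.89-fold) and Hist3h2a (1.89-fold). Adjusted over the list alone, the NRF2 list had 3 lower genes, the amino acid and pericentral lists 1 lower each, the periportal list 3 higher and the histone list 2 higher. Histone genes had an adjusted p of 0.0273 in camera, and of 0.527 with an estimated correlation. Limma called 0 genes of the mitochondrial genome (13 tested), nuclear oxidative phosphorylation (32), interferon response (23), circadian clock (21), insulin signalling (21), endothelial cell (19) and stellate cell (12) lists. At an unadjusted p under 0.05 these lists had 0, 0, 3, 2, 2, 0 and 0 higher genes and 1, 0, 1, 0, 3, 1 and 0 lower genes in that order, and adjusted over the list alone they had 0. Smaller lists with 0 genes called were red blood cells (7 tested), B and plasma cells (6), cholangiocytes (5) and cell cycle (5). At an unadjusted p under 0.05 they had 0, 3, 1 and 0 higher genes and 4, 1, 0 and 1 lower genes in that order. Adjusted over the list alone they had 0, 3, 1 and 0 higher and 0, 1, 0 and 0 lower genes, and camera called none of them. Camera called 21 of 41 lists at the preset correlation, 0 with an estimated correlation, and fry called 7. Those 7 were the hepatocyte, adipocyte, male-biased, female-biased, glycogen, lipoprotein and lipid droplet, and growth hormone lists. The smallest unadjusted camera p with an estimated correlation was 0.0222, for male-biased genes. P-values also rose where the estimated correlation lay below the preset 0.01. For hepatocyte genes (-0.004) the camera p rose from 0.00127 to 0.0236, and for growth hormone genes (-0.012) from 0.0178 to 0.0654. The loss of all calls at this setting therefore does not come from correlation between genes alone.

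The called genes per list were counted again with each library left out in turn, a step chosen after the data were seen, and many counts depended on single libraries. Lower genes of the list of fatty acid oxidation and PPAR alpha targets numbered 4 without knockout replicate 1 and 5 to 7 otherwise. Those of fatty acid synthesis numbered 1 without knockout replicate 1 or 3 or wild type replicate 2. For lipoproteins and lipid droplets 2 to 4 genes were lower, and Lpl kept its call only without knockout replicate 1 or wild type replicate 3. Adipocyte genes had 3 to 4 lower genes. Male-biased genes had 3 higher genes without knockout replicate 1, 2 without knockout replicate 3 or wild type replicate 2, and 10 without wild type replicate 3. Female-biased genes had 2 lower genes without knockout replicate 1 or 2 or wild type replicate 2, and 3 without replicate 3 of either group. Of xenobiotic genes 2 were lower without knockout replicate 1 or 3 or wild type replicate 2, and of p53 targets 1 was lower without any of the knockout libraries or wild type replicate 2. For the growth hormone axis 0 genes were higher without knockout replicate 3 or wild type replicate 2, and 1 without knockout replicate 1 or 2. Endoplasmic reticulum stress had 0 higher genes without knockout replicate 1 or 3 or wild type replicate 1, and 1 without wild type replicate 2. Glycogen metabolism had 0 lower genes without knockout replicate 3 and 1 without knockout replicate 1 or 2 or wild type replicate 1 or 2. Bile acid genes had 2 to 4 higher genes, and Abcc2 kept its call only without wild type replicate 3. Cholesterol synthesis had 4 higher genes, periportal genes 3 and hepatocyte, histone and interferon genes 2 each without wild type replicate 3. Without knockout replicate 3 or wild type replicate 2 each of these 5 lists had 0. Acute phase genes had 0 lower genes without knockout replicate 1 or 3 and 1 without knockout replicate 2 or wild type replicate 2. Immediate early genes had 1 higher gene (Junb) without any of the knockout libraries, since Ier2 lost its call in each case, 0 lower genes without knockout replicate 2 or 3 or wild type replicate 2, and 1 lower gene without replicate 1 of either group. Bhmt of the amino acid list lost its call without knockout replicate 1 or 3 or wild type replicate 2, Rnase4 of the periportal list without the same libraries, and Ahsg and Hist3h2a of the hepatocyte and histone lists without any library except wild type replicate 3. NRF2 targets had 4 lower genes without wild type replicate 1 and 2 without knockout replicate 1 or wild type replicate 3.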

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

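Removal of the transcript length trend, leaving out the genes listed at 0 and the test of other splits of the libraries were chosen after the data were seen, and the other alternatives were planned. Fto had a log2 change of -1.0 and an adjusted p of 0.0975 without a filter on low values, where 18965 genes were tested, and log2 changes of -1.20 to -0.81 (adjusted p 0.0184 to 0.146) when each library was left out. For genes higher in knockout, quantile normalization gave 180, removal of the transcript length trend 216, and leaving out a library 43 to 312. For genes lower in knockout, no filter on low values gave 93, removal of the trend 290, and leaving out a library 49 to 240. Gene lists called were 21 at the preset correlation, 0 with an estimated correlation, 7 with fry, and 19 to 22 when each library was left out; the causes of these differences were not tested. Of 64 called genes besides Fto that were picked by fixed rules, 34 lost their call without a filter and 36 without knockout replicate 3. No paired analysis was possible because the labels share no replicate numbers between the groups. At 68 fragments for 2 kilobases at 1 FPKM, changes of genes below 1 FPKM were measured less precisely.

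The 6 libraries can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split gave 115 higher genes, 172 lower genes and 21 lists, and it was 1 of 10 to do so in each case. The highest of the other splits, counted in either direction since their groups have no order, was 2 for higher genes, 2 for lower genes and 16 for lists.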

Other observations

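The genes in this paragraph and all tests in this part were chosen after the results were seen. The receptor genes Egfr and Lifr rose in knockout, from 15.1 ± 3.14 to 44.5 ± 10.1 FPKM and from 25.2 ± 7.83 to 83.5 ± 2.99 FPKM (SD, n = 3 each; adjusted p 0.0137 and 0.00723 in limma). Of genes on chromosome 4, Zfp992 fell 4.90-fold, Zfp993 5.19-fold, Zfp991 3.29-fold, Zfp982 2.09-fold and Zfp979 5.38-fold (adjusted p 0.00139 to 0.0159). On chromosome 14 the neighbouring copies Tmem254a, Tmem254b and Tmem254c rose 2.83-fold, 2.83-fold and 2.78-fold, and Plac9a and Plac9b rose 3.68-fold and 3.73-fold; reads of such copies cannot be assigned with certainty.

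On chromosome 8, 10 called genes lay between 84249906 and 85075162, among them Mri1, Ier2, Gadd45gip1, Gcdh, Klf1, Junb and Dhps. In a permutation test with 10000 random placements of the calls, as many calls in 1 Mb had a p of 0.0002. This argues against random placement. Loss of 1 copy of the segment would give a median log2 change of -0.86 over its 24 tested genes, and the observed median was -0.045 (95% bootstrap interval -0.60 to 0.19); under a bound of -0.5, written before this median was computed and then replaced, the test would have been undecided. DNA linked to the modified Fto allele, such as a flanking segment from another strain, is a candidate explanation, since only 0.776% of tested genes lie as near to Fto. However, the tested genes from Wdr83 to Aktip lie between the segment and Fto, nearer to Fto, and none of them was called. Of these, Man2b1 and Gpt2 had lower means in knockout with an adjusted p of 0.0650 in limma. On the other side of Fto, the called genes Ces1b, Ces1g, Mt1 and Mt2 also lie nearer to Fto than the segment does. The other tested genes between Fto and Mt1 were not called. The next densest 1 Mb windows lay on chromosomes 14 and 12, with 6 and 4 calls, where linkage to Fto is not possible. The chromosome 14 window consists of the Tmem254 and Plac9 copies and Gm9780, so its 6 calls may not be separate. The densest window of the random draws had a median of 4 calls. These windows therefore weigh little for or against linkage. Called and uncalled genes both lie nearer to Fto than the segment, so nearness alone cannot decide on linked DNA. An effect of FTO loss itself on the genes of the segment stays open and was not tested.

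Cidea, Cidec, Plin4 and Pparg were lower in knockout. Fat tissue in the wild type samples would also bring Adipoq, Plin1 and Lep, but in wild type replicates 1, 2 and 3 Adipoq was at 0.0824, 0.233 and 0.0248 FPKM against 27.8, 35.8 and 36.7 FPKM of Cidea, and the median of the 3 genes was at most 0.0871% of Cidea, which argues against fat as the source of Cidea. Fabp4 and Cfd, other genes of fat, were higher than that: Fabp4 was at 13.3, 18.8 and 39.9 FPKM in these libraries and 10.8 to 13.7 FPKM in knockout (not called), and Cfd at 4.26 to 6.46 FPKM and 0.610 to 1.24 FPKM. A change within liver cells that follows the genotype stays open as a hypothesis and may include feeding or hormonal state, which the labels do not give.

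Ribosomal protein genes had higher means in knockout, with a median log2 change of 0.41 over 34 genes. A transcript length trend could raise short genes together: deviations of wild type replicates 1 and 3 from the gene means correlated with transcript length across 10309 genes (Spearman 0.384 and -0.367; genes are not independent replicates). The median was 0.40 after removal of the trend, which argues against the trend as the whole cause. Without wild type replicate 3 it was 0.57, but that library had the highest ribosomal level of the wild type libraries, so leaving it out was bound to raise the difference and decides nothing. Other differences between RNA samples stay open.

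A hypothesis that imprinted genes rise in general, as Meg3 and Rian did, was tested on 17 other imprinted genes. Of these 17, 0% were called higher in limma (exact 95% interval 0% to 19.5%, with genes taken as independent) and 1 (Copg2) was called lower. Only 115 of all 10405 tested genes were called higher, so 0 calls among 17 genes were likely in any case. The count therefore cannot decide whether there was a smaller general rise. The log2 changes of the 17 ran from -0.57 to 0.18, against 2.56 for Meg3 and 2.41 for Rian, so none rose to a similar extent.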
